A study of Mus musculus with 30 samples.

How the data were processed

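The samples were 30 RNA-seq libraries of mouse CD4 T cells, 3 in each of 10 groups, made from 5 polarised cultures sorted into IL-10 positive and negative compartments; groups and replicate numbers were taken from the sample titles. Per the labels' protocols, libraries were made by an adaptation of the SMART-Seq2 method from 2000 lysed cells each, with poly-A priming. Such amplified libraries carry no molecular identifiers and no strand, so reads of overlapping or antisense genes and of near-identical paralogs, such as the histone, Gbp and Ifit families, may be shared between genes. Per the labels' protocols the sort kept 7-AAD negative, TCR-beta positive, CD4 positive, GFP negative cells; their wording gives Thy1.1 positive for both compartments, and the titles were followed.

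The authors deposited 1 table per library with RSEM's expected counts per gene, which need not be whole, per the file headers. Per the file headers the same deposited tables hold TPM and FPKM, measures scaled for depth and gene length, and the gene length and effective length, another deposited measure, per the file headers; none of these was tested here. RSEM and the mm10 build are named in the submitters' processing notes; the RSEM version and the aligner are not given in the sources used here. RSEM divides reads that match several genes by an estimate, which can move counts between paralogs. All tables list the same 23420 gene symbols. Coordinates came from RefSeq annotation of GRCm38, the assembly that mm10 names.

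Expected counts were rounded to whole numbers. Genes were kept by filterByExpr of edgeR 4.0.16 in R 4.3.3, which left 12611 genes, and libraries were scaled by TMM. edgeR's quasi-likelihood test (glmQLFit and glmQLFTest) was run on 1 fit of all 30 libraries with a mean per group and no covariate, so that groups share an estimate of spread. The p-values were two-sided and adjusted by Benjamini-Hochberg, and genes were called at an adjusted p below 0.05. Contrasts were IL-10 positive minus negative in each culture, their mean, their equality over the 5 cultures, Tr1 minus the mean of the other IL-10 positive groups, and pTh17 minus Th17 within IL-10 positive groups. Standard errors were the log2 fold change over the square root of F. CPM used TMM-scaled library sizes, and log CPM a prior count of 2. A fold against a group at 0 used a floor of 3 counts over that group.

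Gene sets were 24 lists written from general knowledge. Lists with at least 3 tested genes were tested with camera of limma 3.58.1 at a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation and with fry. Groups, tests, the 24 lists and the named-gene rule were set before the data were examined. So were the alternatives in the closing sections, apart from those said there to be chosen later or added. Named genes were Il10 and Thy1; the 12 highest and 12 lowest called genes of the mean comparison with the same sign in 5 cultures and at least 5 CPM; the 8 highest and 8 lowest called genes of each other comparison with groups that do not overlap and at least 5 CPM; the 12 smallest p-values of the test of equality; up to 4 genes per list; and a set of lineage regulators and cytokines. Some genes under this rule are not reported here. Genes known by Gm, LOC or Rik numbers, small RNAs and receptor segments were counted and not named, except within lists. Cd79a and H2-Ab1 in pTh17, Bank1, Siglecg and H2-Ob were named after their values were seen.

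The Th17 IL-10 positive libraries were deeper than the negative ones (mean totals of 9.59 and 5.81 M), and Tr1 IL-10 positive libraries were the shallowest group by mean (5.01 M). The scripts were tested on simulated data with these means and library sizes and 200 changed genes, 50 at each of 1.25, 1.5, 2 and 4-fold. The changed genes were drawn from those above 1 CPM on average in every culture. Every gene was given the spread of the fitted trend, independently in each library. The shares recovered and false need not hold for genes with fewer counts or with a spread off that trend. With changes in Tr1 alone and 12338 genes tested, the Tr1 comparison recovered 26%, 56%, 84% and 100% at these folds, with 3.75% of calls false. The test of equality recovered 10%, 42%, 72% and 100% (3.73% false), and the unchanged Th1 comparison gave 0 calls. With changes in all 5 subsets and 12322 genes tested, the Th1 comparison recovered 22%, 70%, 90% and 100% (4.05% false). The Tr1 comparison then recovered 10%, 60%, 82% and 98% (2.67% false) and the mean comparison 72%, 98%, 100% and 100% (5.38% false). A cell cycle list raised 1.5-fold in Tr1 was called, with 1 of 21 other lists called. The alternatives tried were another size factor, DESeq2 1.42.0, no filter on low counts, each library left out in turn, the title's number as a block, fits of 6 libraries, the IL-10 negative libraries, random thinning to 1 depth, and calls without B cell and myeloid genes.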

Results

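Interleukin 10 (IL-10) is a cytokine that restrains immune responses and that several helper T cell types can make. The 30 RNA-seq libraries came from naive CD4 T cells of C57BL/6 mice with a Foxp3-GFP and an IL-10-Thy1.1 reporter. The cells were activated in culture with 2.5 ug/ml anti-CD3 and irradiated splenocytes depleted of CD4 cells, at 6 feeder cells per T cell. Each of 5 cultures received its own cytokines. Th1 cultures had IL-12 at 20 ng/ml, Th2 cultures IL-4 at 20 ng/ml, and Tr1 cultures, a regulatory type, IL-27 at 25 ng/ml. Th17 cultures of the non-pathogenic kind had TGF-beta 1 at 2 ng/ml and IL-6 at 25 ng/ml. Pathogenic Th17 cultures, written pTh17 here, had IL-1 beta at 20 ng/ml, IL-6 at 25 ng/ml and IL-23 at 20 ng/ml. After 72 h the Foxp3-GFP negative T cells were sorted by the Thy1.1 reporter into IL-10 positive and IL-10 negative compartments, and 2000 cells were lysed per library, with 3 libraries in each of the 10 groups. Total expected counts per library ran from 4394704 to 11850597. Replicate libraries were close, with correlations of log CPM (counts scaled to the TMM-adjusted library total, in the usual CPM unit) from 0.971 to 0.992 over 30 pairs. The spread beyond counting error, edgeR's biological coefficient of variation fitted in each group alone, was 5.48% to 10.6%. Tr1 IL-10 positive replicate 18 stood apart from its 2 replicates, with chi-square per degree of freedom of 12.73 and 14.01 against 3.58 between these 2, and 32.8% of counts in its 10 top genes against 24.9% and 24.6%. The labels do not say that replicates came from separate cultures or animals, so the p-values measure the spread between these libraries, which may be technical. The counts carry no molecular identifiers, so floors quoted below cover counting error only.

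Does Il10 transcript follow the reporter, and do the cultures carry the expected lineage genes? Il10, on chromosome 1 from 131019845 to 131024970 of mm10, was higher in the IL-10 positive libraries of all 5 cultures. Mean Il10 rose from 5.73 ± 1.06 to 380.5 ± 13.1 CPM (SD, n = 3) in Th1 and from 66.2 ± 7.07 to 814.8 ± 57.7 in Th2. Il10 rose from 1.66 ± 1.38 to 23.5 ± 1.71 CPM in Th17, from 0.779 ± 0.426 to 51.6 ± 1.91 in pTh17 and from 0.474 ± 0.435 to 47.4 ± 7.23 in Tr1. The difference by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment had adjusted p from 7.64e-17 in Th17 to 1.34e-28 in Th1. The fitted fold was 13.9 in Th17, or 26.7 without IL-10 negative replicate 12, and 88.5 in Tr1, or 153 without IL-10 negative replicate 18 (edgeR). The Th2 IL-10 negative libraries held more Il10 than the IL-10 positive libraries of Th17 by a log2 fold change of 1.49 ± 0.12 (SE; edgeR, adjusted p = 7.49e-14), a contrast chosen after the values were seen. Thy1, part of the reporter and also a T cell surface gene, was higher in each IL-10 positive group, for example 1224 ± 74.0 against 169.0 ± 10.3 CPM in Th1. Tbx21 and Ifng, the Th1 regulator and its cytokine, stood at 264.9 ± 35.8 and 209.2 ± 7.74 CPM in Th1 IL-10 positive libraries. Tbx21 was not confined to Th1, at 143.3 CPM in Tr1, 110.0 in Th2, 79.0 in pTh17 and 1.97 in Th17 IL-10 positive libraries. Gata3 and Il4, which mark Th2 cells, stood at 1049 ± 40.0 and 32.8 ± 2.05 CPM in Th2 IL-10 positive libraries. Il4 also stood at 10.6 CPM in pTh17 IL-10 positive libraries, and at or below 0.158 in those of Th1, Th17 and Tr1. Il17a, which marks Th17 cells, stood at 91.1 ± 9.69 CPM in Th17 and at 139.5 ± 20.5 in pTh17 IL-10 positive libraries. Foxp3, the regulator of regulatory T cells, stayed at or below 2.50 CPM on average in all 10 groups.

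**Figure D1:**
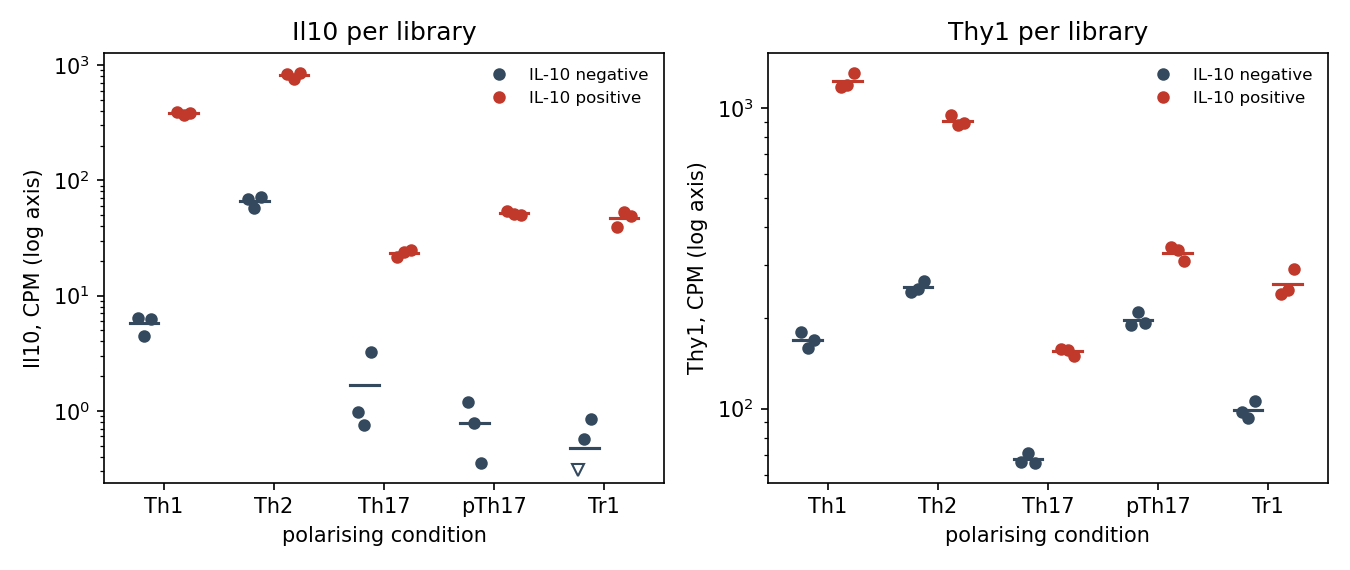
Il10 and Thy1 in CPM (log axes) in each of the 30 libraries, by polarising condition and compartment; points are libraries and bars are means of 3 libraries, and an open triangle on the lower edge is a library at 0. Il10 is higher in the IL-10 positive libraries of each condition, from 23.5 CPM in Th17 to 814.8 CPM in Th2.

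In Th1 cultures the IL-10 positive cells carried more effector and proliferation transcripts and fewer naive cell transcripts than the IL-10 negative cells. Genes of naive and memory-like T cells fell: 15 of 18 were lower and 1 was higher, 15 and 1 adjusted over the list alone, led by Tcf7 (log2 fold change -4.59 ± 0.08, SE), a transcription factor of resting T cells, and the lymph node homing receptor Ccr7 (-3.94 ± 0.07). Cytotoxic effector genes were higher in 12 and lower in 1 of 13, with Gzmb at 4.11 ± 0.12 and Prf1 at 2.53 ± 0.09. Cholesterol synthesis genes rose in all 20 tested (camera, adjusted p = 1.30e-28), with Hmgcs1 at 1.51 ± 0.06, and cell cycle genes in 24 of 26 (camera, adjusted p = 2.26e-24). Co-inhibitory receptor genes were higher in 11 and lower in 3 of 18 (12 and 3 adjusted over the list alone), with Havcr2 at 4.79 ± 0.17 and Pdcd1 at 2.32 ± 0.10. Prdm1 and Maf, regulators of Il10, rose by 2.68 ± 0.16 and 1.58 ± 0.15, and Bach2 changed by -1.66 ± 0.07. Adjusted over the list alone, the counts higher were 12 for cytotoxic, 20 for cholesterol synthesis and 24 for cell cycle genes. Other named genes with large differences were Mmp9 (6.67 ± 0.36, or 7.49 without Th1 IL-10 negative replicate 4) and Ccl5 (5.64 ± 0.22) on the higher side and Dapl1 (-6.73 ± 0.34) and Igfbp4 (-5.44 ± 0.10) on the lower. Genes listed as markers of NK cells, which activated T cells can also express, were higher in 3 of 3 tested, with Klrk1 at 3.52 ± 0.18. Klre1, 1 of the 3, was at 0 in the IL-10 negative libraries and at 10 counts over the positive ones. Its call ended without IL-10 negative replicate 4, 5 or 6 or IL-10 positive replicate 5 or 6 (edgeR, adjusted p = 0.0540 to 0.0965). Of the myeloid list Itgam was at 1.86 ± 0.17. The 2 summed CD8 T cell genes went from 23.0 ± 4.13 to 33.4 ± 3.02 CPM (SD, n = 3), with Cd8a at 1.78 ± 0.36 (SE). The summed B cell list rose from 17.98 ± 2.21 to 51.0 ± 5.23 CPM (SD, n = 3), most of it H2-Ab1, at 12.8 ± 0.741 and 41.8 ± 3.90; 2 of 11 tested genes were higher and 0 lower (2 and 0 adjusted over the list alone), and the list was not called (camera, adjusted p = 0.421). In all, edgeR called 5529 of 12611 genes, 2962 higher and 2567 lower, of which 906 and 593 differed at least 2-fold. The split was 3313 higher and 2214 lower with size factors by median of ratios, 3308 and 2207 with DESeq2, and 3247 and 2022 without the filter on low counts. The libraries of the compartments did not overlap for 51.4% of genes, where chance gives 10%.

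In Th2 cultures IL-10 positive cells carried fewer naive cell transcripts and more transcripts of Th2 and Th1 genes. Naive and memory-like genes fell in 15 of 18 and rose in 0 (16 adjusted over the list alone), with Tcf7 at -2.71 ± 0.07. Th2 lineage genes were higher in 8 and lower in 2 of 12 (camera, adjusted p = 9.13e-04), including Il4 (1.06 ± 0.15) and Ccr8 (1.30 ± 0.11), while Gata3 was not called (0.05 ± 0.07; edgeR, adjusted p = 0.675). Th1 genes rose too, in 10 of 14, with the chemokine receptor Cxcr6 at 2.26 ± 0.11. Of 13 cytotoxic genes 6 were higher and 0 lower (6 and 1 adjusted over the list alone). The summed CD8 T cell genes went from 10.6 ± 1.42 to 18.2 ± 1.02 CPM (SD, n = 3). The summed list of regulatory T cell genes fell from 87.2 ± 0.860 to 50.5 ± 5.87 CPM, although its member Gpr83 rose from 3.31 ± 0.904 to 6.45 ± 0.470. The summed B cell list rose from 43.2 ± 1.96 to 59.0 ± 9.47 CPM, most of it H2-Ab1, at 25.8 ± 0.148 and 40.9 ± 5.62 (SD, n = 3). Gzmb rose by 3.26 ± 0.11 and Il1r2, a decoy receptor for IL-1, by 3.37 ± 0.18. Adjusted over the list alone, 8 Th2 genes were higher and 2 lower, 11 Th1 genes were higher, and 11 interferon-stimulated genes were lower and 4 higher. Cell cycle genes rose in 9 of 26 (10 higher and 1 lower adjusted over the list alone), and the list's median was 0.12 (camera, adjusted p = 0.0272; adjusted p = 0.447 with an estimated correlation). Interferon-stimulated genes were lower in 11 and higher in 3 of 24 (camera, adjusted p = 0.01; adjusted p = 0.138 with an estimated correlation). Prdm1 and Maf rose by 1.45 ± 0.14 and 0.95 ± 0.10. edgeR called 2752 genes, 1555 higher and 1197 lower, of which 317 and 243 differed at least 2-fold. Libraries did not overlap for 38.7% of genes, where chance gives 10%.

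In non-pathogenic Th17 cultures, proliferation, glycolysis and Th17 genes were higher in IL-10 positive cells, and genes of naive and regulatory T cells were lower. All 26 cell cycle genes rose (26 adjusted over the list alone), with a median of 3.10, including Ccna2 (3.67 ± 0.09) and Plk1 (3.59 ± 0.10). Glycolysis genes rose in 16 of 17, with Tpi1 at 2.51 ± 0.07, and cholesterol synthesis genes in 19 of 20. Th17 genes rose in 12 of 13, with Il17f at 3.45 ± 0.09, Il17a at 3.38 ± 0.17 and Il23r at 2.90 ± 0.20. Ahr, a ligand-sensing transcription factor, rose by 1.90 ± 0.17 and its target Cyp1a1 by 2.48 ± 0.14; 4 of 5 listed Ahr targets rose (camera, adjusted p = 0.0138). Maf was not called (0.03 ± 0.10; edgeR, adjusted p = 0.822), and Prdm1 stood at 0.977 ± 0.865 and 0.834 ± 0.963 CPM in the negative and positive groups. Prdm1 was not called (edgeR, adjusted p = 0.704), and single libraries set its sign: it was -1.76 without IL-10 positive replicate 10 (edgeR, adjusted p = 0.0212) and 0.77 without IL-10 negative replicate 11 (edgeR, adjusted p = 0.398). Interferon-stimulated genes were lower in 17 and higher in 2 of 24 (camera, adjusted p = 0.0019; adjusted p = 0.0792 with an estimated correlation), with Irf7 at -2.50 ± 0.17. Cytotoxic genes were lower in 7 and higher in 2 of 13, which the list test did not call (camera, adjusted p = 0.143); Prf1 fell by 4.74 ± 0.25 (SE). Of 5 listed genes of regulatory T cells, 4 were lower (camera, adjusted p = 0.0061), with Gpr83 at -3.64 ± 0.14 and Nrp1 at -1.64 ± 0.16. Foxp3, among them, was lower at -1.47 ± 0.48 (edgeR, adjusted p = 0.0086), a call that ended without Th17 IL-10 positive replicate 10 (edgeR, -1.18, adjusted p = 0.0610). Naive and memory-like genes fell in 14 and rose in 3 of 18. The summed B cell list rose from 10.8 ± 2.22 to 22.8 ± 2.52 CPM and its member H2-Ab1 from 1.63 ± 0.613 to 13.03 ± 1.02 (SD, n = 3), with 4 genes higher and 2 lower of 11 and no call of the list (camera, adjusted p = 0.713). For these lists, counts adjusted over the list alone were equal to those over all genes. edgeR called 7338 genes, 3688 higher and 3650 lower, of which 1416 and 1268 differed at least 2-fold; thinned to one depth the split was 3301 higher and 3369 lower. Libraries did not overlap for 62.4% of genes, where chance gives 10%.

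In pTh17 cultures most listed cytokine and chemokine genes were higher in the IL-10 positive libraries, which also held more transcripts of B cells. Ifng rose by 4.25 ± 0.27, Ccl4 by 2.45 ± 0.12 and Csf1 by 2.83 ± 0.19, and 15 of 24 listed cytokines and chemokines were higher and 2 lower (camera, adjusted p = 5.13e-15). Il21, at a higher level than Ifng, went down from 354.9 ± 26.5 to 258.6 ± 4.10 CPM, where Ifng reached 13.5 ± 2.68 (SD, n = 3). Cxcr6 rose by 3.57 ± 0.17, Maf by 1.90 ± 0.11 and Prdm1 by 1.92 ± 0.16. Th17 genes rose in 10 of 13, and naive and memory-like genes fell in 14 of 18. Adjusted over the list alone, 15 cytokines and chemokines were higher and 3 lower, 10 Th17 genes were higher, 15 naive and memory-like genes were lower and 5 myeloid genes were higher. Of 11 tested B cell genes, 9 were higher and 0 lower (10 adjusted over the list alone; camera, adjusted p = 2.96e-18). Cd79a, a part of the B cell receptor, rose from 0.780 ± 0.467 to 10.6 ± 4.60 CPM, Cd74 from 6.42 ± 0.994 to 49.8 ± 15.5 and H2-Eb1 from 0.329 ± 0.0825 to 21.6 ± 4.99 (SD, n = 3). The summed B cell list stood at 287.8 ± 42.4 CPM in these libraries and at 121.1 ± 5.86 in the pTh17 IL-10 negative libraries, where H2-Ab1 held most of it at 106.8 ± 5.36 CPM. Of 7 tested myeloid genes 4 were higher, with Tyrobp at 3.77 ± 0.69. All 3 tested NK cell genes were higher, also when adjusted over the list alone (camera, adjusted p = 1.03e-04), with Klrk1 at 3.55 ± 0.56, and the summed NK cell list went from 0.675 ± 0.585 to 7.33 ± 2.02 CPM (SD, n = 3). The sort had kept TCR-beta positive, CD4 positive cells, per the labels' protocols. edgeR called 2327 genes, 1277 higher and 1050 lower, of which 324 and 91 differed at least 2-fold. Leaving out the listed B cell and myeloid genes gave 2305. That step drops only the listed genes, so it does not show that the other calls come from T cells. Libraries did not overlap for 32.7% of genes, where chance gives 10%.

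**Figure D2:**
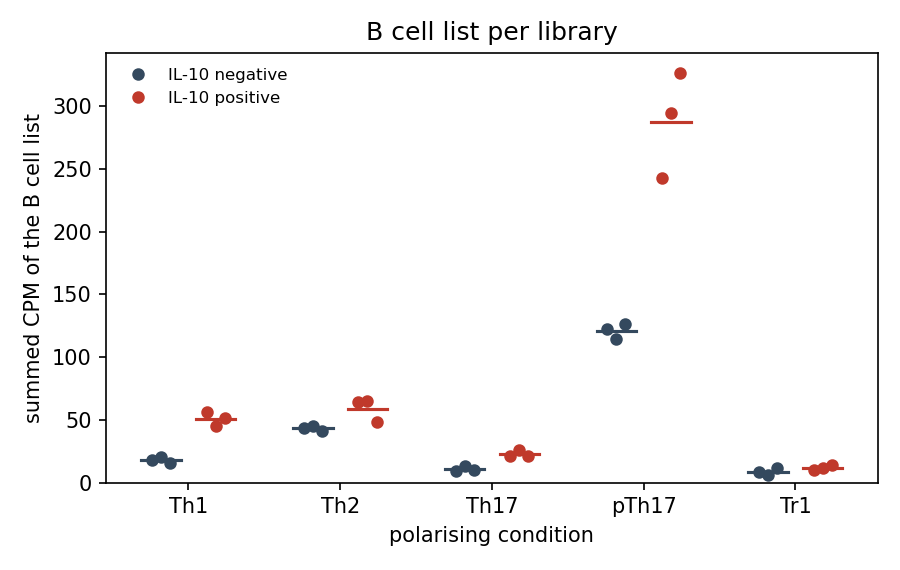
Summed CPM of the 14 listed B cell genes in each library, by polarising condition and compartment; points are libraries and bars are means of 3. The pTh17 IL-10 positive libraries average 287.8 CPM and the pTh17 IL-10 negative libraries 121.1 CPM.

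In Tr1 cultures the IL-10 positive cells were set apart by cell cycle and cytotoxic genes. All 26 cell cycle genes rose, with a median of 2.52; Ccna2 rose by 5.49 ± 0.14 and Mki67 by 3.36 ± 0.13. Gzmb, which encodes the protease granzyme B, rose by 7.57 ± 0.18, and 11 of 13 cytotoxic genes rose (camera, adjusted p = 2.44e-18). Markers of CD8 T cells rose too: Cd8a went from 3.39 ± 1.64 to 12.2 ± 3.48 CPM and Cd8b1 from 21.6 ± 3.60 to 34.9 ± 3.38 (SD, n = 3). Ccl5 rose by 5.97 ± 0.14 and Ccl4 by 4.79 ± 0.16, and of 24 listed cytokines and chemokines 6 were higher and 3 lower (camera, adjusted p = 3.26e-07). With the 10 members that had a group at 0 set at their bound, the median of that list was 0.10, against 1.23 as fitted. Co-inhibitory receptor genes were higher in 9 and lower in 3 of 18 (camera, adjusted p = 2.39e-08), with Tigit at 3.05 ± 0.12, Lag3 at 1.41 ± 0.06 and Entpd1 at 3.69 ± 0.20. Maf and Prdm1 rose by 1.52 ± 0.14 and 2.24 ± 0.27, and Tbx21 by 1.29 ± 0.13. Naive and memory-like genes fell in 16 of 18, with Igfbp4 at -3.36 ± 0.11. Adjusted over the list alone, 26 cell cycle, 11 cytotoxic and 11 co-inhibitory receptor genes were higher, 7 cytokines and chemokines were higher and 3 lower, and 17 naive and memory-like genes were lower. Klrk1, an NK cell receptor gene, rose by 3.61 ± 0.19, and Itgam of the myeloid list by 2.08 ± 0.25. Hist2h3c2 was at 0 in all 3 IL-10 negative libraries and at least 35.4-fold higher in the positive ones, against a floor of 3 counts over the group. edgeR called 4377 genes, 2591 higher and 1786 lower, of which 1092 and 254 differed at least 2-fold, with 3664 called without IL-10 positive replicate 18, and libraries did not overlap for 41.3% of genes, where chance gives 10%. Without the filter on low counts the split turned to 2058 higher and 2340 lower.

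Averaged over the 5 cultures, IL-10 positive cells expressed more cell cycle, cholesterol synthesis and glycolysis genes and fewer genes of naive T cells. Besides Il10 (5.19 ± 0.09), genes higher in each culture included the chemokine gene Ccl4 (3.25 ± 0.10), the metal-binding protein gene Mt1 (3.10 ± 0.11) and Tigit (1.86 ± 0.05). Genes lower in each included Dapl1 (-4.49 ± 0.14), Igfbp4 (-2.95 ± 0.04) and Tcf7 (-2.32 ± 0.03). Igfbp4 lies on chromosome 11 from 99040005 to 99052655 and Tcf7 on chromosome 11 from 52246527 to 52283383 of mm10. The naive and memory-like list was lower in 17 of 18 genes (camera, adjusted p = 6.25e-59), and all 26 cell cycle genes were higher, with a median of 1.53. All 20 cholesterol synthesis genes were higher, as were 16 of 17 glycolysis genes with 1 lower (camera, adjusted p = 3.04e-16 for both lists). These averages came mainly from Th1, Th17 and Tr1. In Th2 and pTh17 the medians were 0.12 and 0.48 for cell cycle, 0.23 and 0.10 for cholesterol synthesis and 0.25 and 0.05 for glycolysis. In the other cultures they ran from 0.43 for glycolysis in Tr1 to 3.10 for cell cycle in Th17. Cytotoxic genes, higher in 7 and lower in 1 of 13, and cytokines and chemokines, higher in 8 and lower in 2 of 24, were not called as lists in this average (camera, adjusted p = 0.432 and 0.141). Adjusted over the list alone, 17 naive and memory-like genes were lower, and 26 cell cycle, 20 cholesterol synthesis, 16 glycolysis, 7 cytotoxic and 8 cytokine and chemokine genes were higher, with 2 cytotoxic and 1 cytokine or chemokine gene lower. edgeR called 7295 genes, 3736 higher and 3559 lower, of which 681 and 246 differed at least 2-fold. In 104 tested genes both groups of at least 1 culture were at 0, so that the average over cultures has no meaning for them; Ifng, Il4 and Il17a are among these.

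The cultures shared more of these genes than independent lists of the same sizes would. In the same direction, 3120 genes were called in at least 3 of the 5 cultures (1744 higher and 1376 lower), against 972.5 expected, and 399 were called in all 5, against 3.05. Of 9916 genes called in any culture, 1697 (17.1%) were called in opposite directions in different cultures. Across genes, which are not independent replicates, the Pearson correlation of log2 fold changes between pairs of cultures ran from 0.137 for Th2 with Tr1 to 0.397 for Th1 with Tr1, over 10 pairs. No library is shared between these 5 comparisons, but the same fit gives each gene the same spread in all of them. The expected counts take every gene as equally likely to be called. Genes that are easier to call in every culture may therefore add to the excess. List tests were run in each culture, for the mean, for Tr1 against the others and for pTh17 against Th17. Of these, 104 calls by camera with the preset correlation became 86 with an estimated correlation. Tests of a list's change between pairs of cultures are not in this count.

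**Figure D3:**
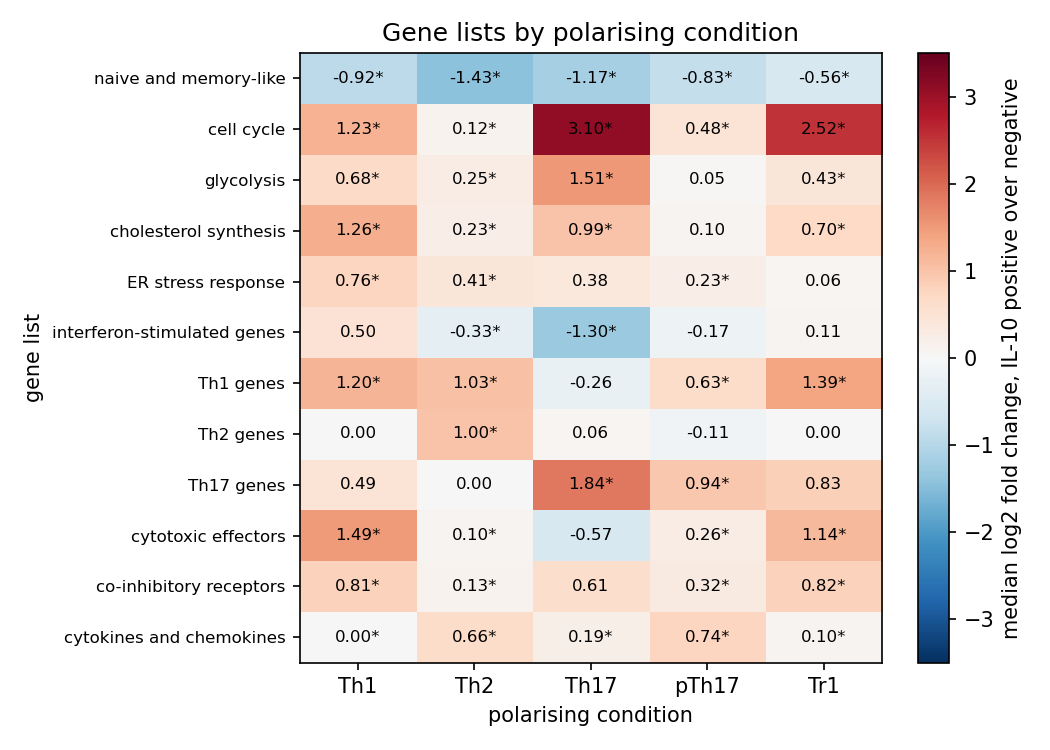
Median log2 fold change of 12 gene lists, IL-10 positive over negative, for each polarising condition, on a colour scale; members with a group at 0 enter at their bound, and a star marks a list that camera calls at adjusted p below 0.05 with the preset correlation. The naive and memory-like list is lower in all 5 conditions, from -1.43 in Th2 to -0.56 in Tr1.

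Where the IL-10 difference itself differed between cultures, Ccna2, Ccr7, Lgals3 and Tcf7 had the smallest p-values among named genes. The test of equal differences (edgeR) called 7651 genes, or 7621 without the 104 genes at 0 in both groups of a culture. Ccna2 differed by 5.49 ± 0.14 in Tr1 and by 0.24 ± 0.07 in Th2, and the change of the cell cycle list was larger in Th17 than in Th2 (camera, adjusted p = 8.06e-92; adjusted p = 7.85e-06 with an estimated correlation). Lgals3, which encodes galectin-3, was higher in Tr1 (3.65 ± 0.11) and Th1 (2.94 ± 0.07) and lower in Th2 (-0.27 ± 0.07). Il21r and Gbp4 were higher in Th1 (1.06 ± 0.06 and 1.29 ± 0.07) and lower in Th17 (-1.94 ± 0.06 and -3.10 ± 0.10). Cytotoxic genes changed differently in Th17 and Tr1 (camera, adjusted p = 7.96e-06; adjusted p = 0.0054 with an estimated correlation). Among regulators, Maf ran from 0.03 ± 0.10 in Th17 to 1.90 ± 0.11 in pTh17, and Ahr from -0.85 ± 0.24 in pTh17 to 1.90 ± 0.17 in Th17. The Ahr call in pTh17 ended without IL-10 positive replicate 13 (edgeR, -0.76, adjusted p = 0.0604) or 15 (edgeR, -0.76, adjusted p = 0.0554), and with libraries thinned to one depth (edgeR, -0.70, adjusted p = 0.0660), where the fold stayed near its size.

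**Figure D4:**
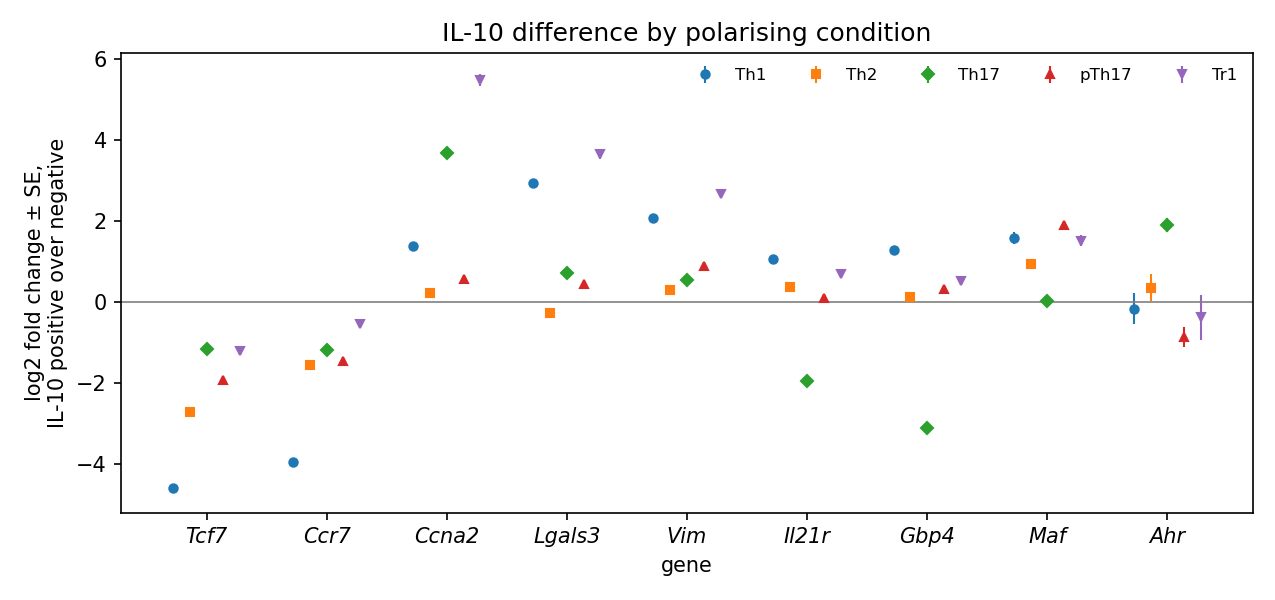
Log2 fold change with its standard error, IL-10 positive over negative, of 9 genes in each of the 5 polarising conditions; symbols stand for conditions and the grey line marks no difference. Il21r and Gbp4 lie above 0 in Th1 and below 0 in Th17.

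Tr1 IL-10 positive cells, compared with the mean of the other IL-10 positive groups, carried more interferon-response and naive cell genes and fewer genes of metabolism and growth. Interferon-stimulated genes were higher in 20 of 24 and lower in 0 (camera, adjusted p = 5.09e-23), with Ifit1 at 4.87 ± 0.20. The chemokine gene Ccl5 was higher by 7.07 ± 0.09. All 20 cholesterol synthesis genes, 16 of 17 glycolysis genes and 25 of 26 cell cycle genes were lower, for example Fdps (-2.64 ± 0.07), Pkm (-1.87 ± 0.05) and Mcm3 (-2.01 ± 0.08). Naive and memory-like genes were higher in 13 and lower in 4 of 18, with Tcf7 at 2.52 ± 0.05. For these lists, counts adjusted over the list alone were equal to those over all genes. Il10 itself was lower than this mean (-1.55 ± 0.10, edgeR, adjusted p = 3.36e-16), as was Maf (-0.77 ± 0.09). Not every group was above Tr1. Il10 stood at 47.4 CPM in Tr1, at 23.5 in Th17 and 51.6 in pTh17, and at 380.5 in Th1 and 814.8 in Th2. Maf stood at 44.6 CPM in Tr1, at 30.6 in Th1, and at 75.2, 140.8 and 105.0 in Th2, Th17 and pTh17. The NK receptor gene Klrk1 (4.74 ± 0.15) was higher and the B cell list gene H2-Ab1 (-4.17 ± 0.17) was lower. Th1 exceeded Tr1 in Klrk1, at 82.4 against 61.9 CPM. Klrk1 stood at 0.784, 0.187 and 2.11 CPM in Th2, Th17 and pTh17 IL-10 positive libraries. edgeR called 8271 genes, 4201 higher and 4070 lower, of which 1873 and 1449 differed at least 2-fold. Tr1 libraries did not overlap the 12 others for 25.7% of genes, against 0.440% if all these libraries were interchangeable. Libraries of a culture lie close together, so the 0.440% does not cover chance differences between whole cultures, which are not excluded. Without the filter on low counts edgeR called 11451 genes and the median of all genes moved to 0.20.

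Pathogenic against non-pathogenic Th17 IL-10 positive cells showed more Th1, cytotoxic and cholesterol genes and fewer Ahr-pathway genes in pTh17. All 15 tested genes of the pathogenic Th17 signature, a list taken from general knowledge of such cells, were higher (camera, adjusted p = 6.42e-26). Tbx21 was at 5.32 ± 0.20 and Ccl4 at 5.69 ± 0.16. Csf2, also on that list, had too few counts to be tested, at 0.0794 ± 0.137 CPM in pTh17 IL-10 positive libraries (SD, n = 3). Ifng was at 0 in the Th17 libraries and at least 142-fold higher in pTh17, against a floor of 3 counts over the group. All 14 Th1 genes and all 20 cholesterol synthesis genes were higher, with Cxcr3 at 3.54 ± 0.17 and Hmgcs1 at 2.79 ± 0.07. Cytotoxic genes were higher in 10 and lower in 2 of 13 (camera, adjusted p = 2.28e-15). Both CD8 T cell markers were also higher, Cd8b1 by 1.56 ± 0.17 and Cd8a by 1.32 ± 0.35. Of 3 NK cell genes 1 was higher, Klrk1 at 3.36 ± 0.51, or 4.24 without Th17 IL-10 positive replicate 12, and 1 was lower. Ahr (-4.03 ± 0.21) and 4 of its 5 listed targets were lower, with Cyp1a1 at -5.40 ± 0.19. Prdm1 was higher by 6.18 ± 0.24, or 7.67 without Th17 IL-10 positive replicate 10, and Nt5e, which encodes CD73, was lower (-6.75 ± 0.17). Il10 was higher by 1.13 ± 0.12, whereas in the IL-10 negative libraries its difference was -1.09 and missed the threshold (edgeR, adjusted p = 0.0513). All 11 B cell list genes and 6 of 7 myeloid genes were also higher in pTh17. Each of these list counts was equal when adjusted over the list alone. edgeR called 7151 genes, 3505 higher and 3646 lower, of which 1775 and 658 differed at least 2-fold; the split was 3663 higher and 3436 lower with size factors by median of ratios, 3651 and 3409 with DESeq2, and 3629 and 3529 without the filter on low counts. Leaving out the listed B cell and myeloid genes alone gave 7119, which does not show that the other calls come from T cells. Libraries did not overlap for 62.6% of genes, where chance gives 10% if libraries are interchangeable. That figure does not cover chance differences between the whole cultures.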

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

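Of the tests below, those of feeder RNA, of the activation list and of IL-10 positive cells in the Th2 negative sort were chosen after the result was seen. Thinning, used below for cell cycle genes and Il10, was also chosen after seeing the data. The second B lineage list was added to the lists set beforehand. The IL-10 difference differed between cultures, by the edgeR test of equal differences, for 7651 genes. Named genes were picked out by that difference, with an adjusted p by edgeR of 9.34e-27 for Ccna2, 1.57e-26 for Ccr7, 5.51e-26 for Lgals3, 7.48e-26 for Tcf7, 7.85e-26 for Ms4a4b and 1.03e-25 for Il21r. It was 3.36e-25 for Folr4, 3.94e-25 for Serpinb5, 4.66e-25 for Gbp4, 1.13e-24 for Ggt1 and 1.13e-24 for Vim by edgeR. Among regulators and cytokines, the adjusted p by edgeR was 1.56e-07 for Tbx21, 4.69e-11 for Gata3, 3.03e-17 for Il21, 6.99e-13 for Maf, 1.17e-05 for Prdm1 and 4.65e-09 for Ahr. For the sorted gene and the reporter it was 6.37e-13 for Il10 and 1.35e-19 for Thy1 by edgeR.

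B cell genes were higher in the pTh17 IL-10 positive libraries. The summed list also rose in Th1 and Th17, where it was not called (camera, adjusted p = 0.421 and 0.713). In Th2 it went from 43.2 ± 1.96 to 59.0 ± 9.47 CPM (SD, n = 3), of which H2-Ab1 alone held 25.8 and 40.9. The tests here cover pTh17 alone. In a second list of 20 B lineage genes written before its values were seen, 8 of 15 with enough counts to test were higher. Bank1 and Siglecg were among them, and H2-Ob was lower. The share was 53.3%, just over the majority set as the criterion, against 10.1% of all genes. Genes could reach enough counts through the pTh17 IL-10 positive libraries alone, which favours genes that are high there. Of all 20 listed genes, 8 are under a majority. B cells carried through the sort are a candidate explanation, although the sort kept TCR-beta positive, CD4 positive cells. RNA from the feeder present alike in both compartments would leave the summed list equal; over all 14 listed genes its log2 ratio was 1.249 ± 0.129 (SE), with 242.6 CPM in the lowest positive and 126.4 in the highest negative library. H2-Ab1 alone held 142.2 of 287.8 CPM in the positive and 106.8 of 121.1 in the negative libraries. The sum of the other 13 genes therefore rose by more than this ratio, though not each gene did. Ebf1 went from 2.81 to 4.86 CPM. The ratio restates the pattern and so argues against RNA alike in both and nothing wider. Feeder RNA that differed between the compartments stays open. No biological explanation was tested.

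Cell cycle genes were higher in IL-10 positive Th17 and Tr1 cells. After thinning all libraries to the same depth the Th17 median was 3.11 (3.10 before), with 26 of 26 genes still called higher. The calls therefore do not need the greater depth of the Th17 positive libraries. Random thinning keeps each gene's expected share of a library, so it could hardly move the median. It does not decide whether depth shaped the fold. Less activated cells in the negative compartment may contribute, but the activation list was called higher in Tr1 and not in Th17 (largest adjusted p of the camera test with an estimated correlation 0.404), so this stays open. Both compartments of a culture had the same cytokines and activation. A difference that goes with IL-10 itself, by which the cells were sorted, is also open and was not tested.

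Il10 in the Th2 IL-10 negative libraries exceeded that in 3 IL-10 positive groups. After thinning, its log2 fold change over Th17 IL-10 positive libraries was 1.48 ± 0.13 (SE). Over pTh17 and Tr1 it was 0.34 ± 0.11 and 0.38 ± 0.12 (edgeR, adjusted p = 0.0096 and 0.0039). The calls thus hold at equal depth. Random thinning keeps expected shares and could hardly move these folds, so it does not decide on depth as their cause. If IL-10 positive cells in the negative sort brought all of its Il10, which stood at 8.12% of the positive level, they would bring at least that share of every other gene; among 3586 genes of 50 CPM or more the lowest ratio besides Il10 was 10.5%, for Gzmb, so such cells remain a candidate. A real difference between Th2 and the other cultures is also open and was not tested.

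Regroupings of the libraries were counted for each number of calls. With 3 libraries against 3 there are 10 splits, too few for a share under 0.05; in each comparison of 6 libraries 1 split, the real one, gave as many calls, and the highest of the others was 1 call in Th1, Th17 and pTh17 and 0 in Th2, Tr1 and pTh17 against Th17. Over 100 splits within cultures, chance was excluded for the mean of 5 cultures (7295 calls, highest other 4947), since 1 split, the real one, gave as many. The real split also stood alone for the differences between cultures (7651, highest other 5478) and for genes shared by at least 3 cultures (3120, highest other 98). Splits within cultures break the IL-10 difference of each culture itself. They therefore cannot decide whether that difference is unequal between cultures, or shared beyond each culture having calls of its own. Over 100 splits of the 15 IL-10 positive libraries chance was excluded for single libraries in Tr1 against the others (8271 calls, highest other 2432). Such splits mix the cultures, whose libraries lie close together, so chance differences between whole cultures are not excluded. The splits within cultures likewise take the libraries as independent, which the labels do not say.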

How the results depend on the processing

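Thinning to the same depth and leaving out B cell and myeloid genes were chosen after seeing the data. The number of calls of all 9 comparisons stayed within 1.5 times its value under another size factor, DESeq2, no filter, thinning, fits of 6 libraries, the IL-10 negative libraries and each library left out, where each was run, and so did the number of shared genes under DESeq2, thinning and the block. Leaving out each library gave 4809 to 5160 calls in Th1, 2143 to 2422 in Th2, 6668 to 7012 in Th17, 1867 to 2066 in pTh17, 3664 to 4207 in Tr1, 7102 to 7287 for the mean, 7356 to 7701 for the differences, 7714 to 8592 for Tr1 against the others and 6557 to 6765 for pTh17 against Th17. In the titles the same number stands on a positive and a negative library, but no shared effect of it was seen. Over 15 pairs the correlation of deviations ran from -0.046 to 0.055. Of these, 6 correlated best with their own number, among them Th2 numbers 7, 8 and 9. Whether libraries of the same number came from the same culture stays open. With the number as a replicate block the calls were 5467 in Th1, 2777 in Th2, 7246 in Th17, 2322 in pTh17, 4315 in Tr1, 7242 for the mean and 7405 for the differences, with 3133 shared genes.

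List calls numbered 104 by camera, 86 with an estimated correlation and 163 by fry, which tests a list alone and not against other genes. In the IL-10 negative libraries the sign of 15 gene results turned, of which 10 were called there, and the cause was not tested. For Tr1 against the others the log2 fold change there was -0.58 for Ctsw, -3.00 for Gzmb, 0.034 for H2-Eb1 (edgeR, adjusted p = 0.968), -0.14 for Itgam (adjusted p = 0.661) and -0.36 for Nrp1. For pTh17 against Th17 it was -0.13 for Cd8a (edgeR, adjusted p = 0.790), -2.11 for Gpr83, -0.27 for Ikzf2 (adjusted p = 0.621), -1.09 for Il10 (adjusted p = 0.0513), 1.29 for Il21, -1.84 for Klrk1, 0.57 for Mcm2, 1.39 for Mcm3, 1.10 for Mcm5 and -0.36 for Zfp36. Thinned to the lowest depth, calls fell to 4961 in Th1, 2131 in Th2, 6670 in Th17, 1975 in pTh17 and 3940 in Tr1, so depth limits the number of calls.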

Other observations

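Other groups of genes moved with IL-10. Genes of the endoplasmic reticulum stress response were higher in the IL-10 positive cells of Th1 (15 higher and 1 lower of 18; camera, adjusted p = 1.93e-12) and Th2 (16 higher and 0 lower; camera, adjusted p = 6.85e-10), with the chaperone gene Hsp90b1 at 1.40 ± 0.06 and 0.51 ± 0.06 (log2, SE). Immediate stress genes were lower in Tr1 (6 lower and 2 higher of 13; camera, adjusted p = 3.25e-04). Adjusted over the list alone, 15 and 17 stress response genes were higher in Th1 and Th2, with 1 lower in each, and 8 immediate stress genes were lower in Tr1. Csf2 and Il9, cytokines of activated helper cells, stood at or below 0.166 and 0.162 CPM on average in all 10 groups. Tr1 IL-10 positive libraries, the group with the lowest mean depth, had counts for 17285 ± 310 genes, against 15633 ± 192 in the Tr1 IL-10 negative libraries (SD, n = 3).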
